A study of Homo sapiens with 6 samples.

How the data were processed

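Total RNA of HuH-7 cells was extracted with TRIzol 48 h after siRNA transfection and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. That kit as named does not mark strand, and the strand setting of the counting is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene could not be told apart. The submitters' processing notes name HISAT2 and DESeq2, without versions or roles, and the genome build hg38. The read counter and the annotation release are not given in the sources used here.

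The deposited values per library have the unit of a signal: they are read counts per gene divided by 1 size factor per library, with no scaling to gene length. This was worked out from the values. In each of the 6 columns 100.0% of the values came out as whole reads to within 0.001 reads, at size factors of 0.946 to 1.125. The deposited signal per group is the authors' mean of 3 such values. The log2 fold changes (si-SLC37A3 over si-NC), p-values and adjusted p-values of the authors' deposited tables were taken as given. The authors' adjusted p-values ran over all genes of the longer table, 2 of which have none. That table holds 27950 rows, 445 of them named as unannotated transcripts and belonging to no Ensembl gene. The table with values per library holds 6262 genes, of which 6248 carry a KEGG gene number; 55 lines that were overflow of long annotation cells were left out. The KEGG annotation in the authors' file was used for 1 pathway test.

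The 6 libraries fall into 2 groups of 3 by their titles. Recovered reads over the 6262 genes were 11928877, 11292272 and 11123140 in si-NC replicates 1, 2 and 3 and 10338054, 11302811 and 12448383 in si-SLC37A3 replicates 1, 2 and 3. No pair of replicates was a duplicate: their recovered reads differed by a chi-square of 6.07 to 19.9 per degree of freedom. The labels name no molecular identifiers, so depth describes reads, not molecules. Pearson correlations of log2 values between libraries were 0.984 to 0.989.

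The test was limma-trend on log2(value + 1), with a minimum mean of 1 normalized count over the 6 libraries, on group alone, with Benjamini-Hochberg adjustment over the 6051 genes left and a threshold of 0.05. A fold change is a difference of group means on the log2(value + 1) scale and, in low genes, can lie below or above the authors' deposited one. MYO1G had 1.97 against 2.14 in the authors' deposited table, and KCNN4 had -2.05 against -1.70. This is the form the design, fixed before the data were examined, gives for normalized values; it names a count test for counts. The prior degrees of freedom came out infinite, so the variance of each gene was taken wholly from the trend over expression, and a gene with an unusual spread between libraries is not penalised for it. Gene lists were tested with camera (preset correlation 0.01, at least 5 members tested) on the same values, with an estimated correlation and fry as alternatives. The genes named in the text were chosen by a rule fixed beforehand: SLC37A3; the 12 greatest increases and 12 greatest decreases among called genes with a mean of at least 2, groups that did not overlap and an approved-style symbol; up to 2 called members per list in each direction, or otherwise the 2 with the highest levels; and the most abundant marker in lists of other cell types and RNA quality. Some genes that the rule took are not reported here.

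Alternatives fixed beforehand were a pseudocount of 0.1, no low-value filter, an adjusted p under 0.01, the replicate number as a block, each library left out in turn, and the other list tests. Added after seeing the data were edgeR's quasi-likelihood test (with TMM, RLE or library totals, no filter, a filter of 50 reads in 3 libraries, a block, or glmTreat against a log2 fold change of 0.5) and DESeq2 on recovered reads, a robust variance prior, library-total scaling, and values corrected for each library's trend on transcript GC content. Library totals are sums over the 6262 genes (in edgeR, over those of them that passed its filter), not over whole libraries. edgeR called 205 genes and DESeq2 200 on recovered reads. Transcript length, GC content, 3′ UTRs, coordinates and exonic overlap came from GENCODE 29 on GRCh38, which is the build hg38 names; the annotation may differ from the authors'. Of the 6262 genes, 6257 matched a transcript. A 3′ UTR scan of 7-mers against the authors' deposited log2 fold changes used 9300 genes with a mean of at least 100 normalized counts and a 3′ UTR of at least 100 bases, with 3′ UTR length and GC content as covariates.

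The scripts were tested on simulated data. With 200 genes changed in counts drawn from the real means and library sizes, limma-trend over 6038 genes recovered 73% of 100 genes changed by 0.5 on the log2 scale and 93% of 100 changed by 1, with 7 false calls among 173. A list shifted by -0.3 was recovered by camera among 39 lists (adjusted p = 1.07e-11), with 1 other list called. The simulated genes were drawn independently, whereas the estimated correlation reached 0.594 in a list called below, and the shift was larger than the median of any called list. The run therefore does not show how often camera falsely calls lists of correlated genes. In 20 of 20 simulated runs over the 9300 genes, a 7-mer with a shift of -0.1 had the lowest score. Those 7-mers stood in 200 to 400 genes each. The lower 7-mer reported below has a smaller shift, -0.036 in 1453 genes, and the runs do not show recovery at that size. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.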

Results

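HuH-7 is an established human hepatocellular carcinoma cell line with hepatocyte features. The cells had been grown in 6-well plates and transfected with a small interfering RNA against SLC37A3 (si-SLC37A3) or with a negative-control siRNA (si-NC), and total RNA was collected 48 h later, with 3 libraries in each of the 2 groups. SLC37A3 belongs to the SLC37 family of sugar-phosphate transporters and forms a lysosomal complex with ATRAID that releases nitrogen-containing bisphosphonates into the cytosol. The series addresses the part SLC37A3 plays in hepatocellular carcinoma, and its design implies one comparison, si-SLC37A3 against si-NC. Values per library were analysed for 6262 genes, of which 6248 carry a KEGG gene number. A longer deposited table of 27950 rows gave group means, fold changes and adjusted p-values without values per library; 445 rows were unannotated transcripts, and 2 had no adjusted p. The reads recovered for the 6262 genes came to between 10338054 and 12448383 per library, which is part of each library: these genes held 64.0% of the mean normalized counts of all genes in si-NC and 63.3% in si-SLC37A3. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

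The target gene was lower in the cells transfected with its siRNA, by a modest amount. In the authors' deposited table, SLC37A3 (ENSG00000157800; GRCh38 chromosome 7, 140293693 to 140404433, minus strand) had a mean of 350.0 normalized counts in si-SLC37A3 and 489 in si-NC. That is a log2 fold change of -0.48, or a change of -28.3%, with an adjusted p of 0.0272 in that table. SLC37A3 was not among the genes with values per library, so its spread between replicates was not analysed here. The family members SLC37A1 and SLC37A2 and the partner gene ATRAID did not pass in the authors' deposited table, with log2 fold changes of -0.15, 0.036 and -0.097. SLC37A4, the glucose-6-phosphate transporter of the endoplasmic reticulum, averaged 1003 ± 78.7 normalized counts in si-SLC37A3 and 1170 ± 113 in si-NC (SD, n = 3 each; limma, log2 fold change -0.22 ± 0.10 SE, adjusted p = 0.248). It was the 1 member of its list with values per library, so its p-value adjusted over the list alone, which was under 0.05, is an unadjusted one, and the groups overlapped.

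Among 6051 genes with a mean of at least 1 normalized count, 99 were higher and 115 were lower in si-SLC37A3 than in si-NC (limma-trend, Benjamini-Hochberg adjusted p under 0.05). The median absolute log2 fold change of the called genes was 0.41, and 16 genes changed at least 2-fold. In 194 of the 214 called genes all 3 libraries of one group lay above all 3 of the other, or 90.7%. The test favours genes with separated groups, so that share is no separate evidence for the calls. Of all genes tested, 16.4% were separated in this way, where chance gives 10%. The counts depended on single libraries: 36 genes passed without si-NC replicate 1, 70 without si-NC replicate 2 and 105 without si-SLC37A3 replicate 1. The count was 151 without si-SLC37A3 replicate 3, 268 without si-NC replicate 3 and 277 without si-SLC37A3 replicate 2. With library totals over the 6262 genes in place of the authors' size factors, 83 genes were higher and 46 lower. Then 64.3% of the calls were higher, against 46.3% with the size factors. Of the 61 called genes that the naming rule took, 20 kept the call without si-NC replicate 1 and 44 kept it after correction for GC content, and DKK4, LCK, NGFR and PRF1 kept it under every alternative tried.

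The strongest increases included DKK4, ADH4, SLC40A1 and STX12. DKK4, which encodes a secreted inhibitor of Wnt signalling, averaged 208 ± 23.3 normalized counts in si-SLC37A3 and 57.1 ± 12.7 in si-NC (SD, n = 3 each), a 3.64-fold difference (limma, log2 fold change 1.86 ± 0.19 SE, adjusted p = 8.54e-19). The alcohol dehydrogenase gene ADH4 was 1.77-fold higher, at 873 ± 189 against 485 ± 38.1 (SD, n = 3 each; limma, adjusted p = 4.19e-11). SLC40A1, the gene of the iron exporter ferroportin, was 1.65-fold higher, at 1663 ± 59.8 against 1011 ± 84.0 (SD, n = 3 each; limma, adjusted p = 4.77e-11). STX12, which encodes an endosomal syntaxin, was 1.67-fold higher (limma, adjusted p = 2.21e-06). TNFRSF11B, the gene of the decoy receptor osteoprotegerin, was 1.70-fold higher, and UGT2B11, a UDP-glucuronosyltransferase gene of a family of close paralogs, was 1.67-fold higher. The zinc-finger genes ZNF26, ZNF616 and ZNF267 were 1.81-fold, 1.74-fold and 1.73-fold higher. The phosphodiesterase gene PDE11A was 1.73-fold higher, and 26.4% of its annotated exonic bases are shared with other annotated genes. MYO1G and RAG1 had the other large increases, 3.92-fold and 3.07-fold on the log2(value + 1) scale, from low levels of 5.75 ± 2.57 and 4.77 ± 2.34 normalized counts in si-NC (SD, n = 3 each). Some of these calls depended on the processing: ZNF616 lost its call under 18 of 22 alternatives, PDE11A under 13 of 22, TNFRSF11B under 10 of 22 and RAG1 under 14 of 20.

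The strongest decreases included NGFR, LCK, PRF1 and INHBB. NGFR, the low-affinity neurotrophin receptor gene, averaged 51.9 ± 12.3 normalized counts in si-SLC37A3 and 173 ± 22.2 in si-NC (SD, n = 3 each; limma, log2 fold change -1.74 ± 0.20 SE, adjusted p = 8.86e-15), and 27.1% of its annotated exonic bases are shared with other annotated genes. LCK, a Src-family tyrosine kinase gene best known from T cells, averaged 26.9 ± 7.46 against 80.6 ± 7.01 (SD, n = 3 each; limma, log2 fold change -1.57, adjusted p = 9.04e-07). PRF1, the perforin gene, had a log2 fold change of -1.24, from 177 ± 30.5 in si-NC to 73.6 ± 6.78 in si-SLC37A3 (SD, n = 3 each; limma, adjusted p = 1.84e-08). INHBB, which encodes an inhibin and activin subunit, had a log2 fold change of -1.16, AHNAK2 of -1.23, the keratin gene KRT15 of -1.01, the collagen gene COL1A1 of -0.98 and the integrin gene ITGA3 of -0.93. The other 4 genes, the potassium channel gene KCNN4, the ephrin gene EFNB3, the Wnt ligand gene WNT6 and the histone gene H2AC18, had log2 fold changes of -2.05, -1.80, -1.48 and -1.45, from means of 15.8, 14.7, 19.4 and 20.3 normalized counts in si-NC. Their calls were lost under 14, 12, 12 and 13 of 20 alternatives, among them edgeR on recovered reads for KCNN4 (adjusted p = 0.0918), and the call of KRT15 under 11 of 21. H2AC18 has near-identical copies that counting could split.

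**Figure D1:**
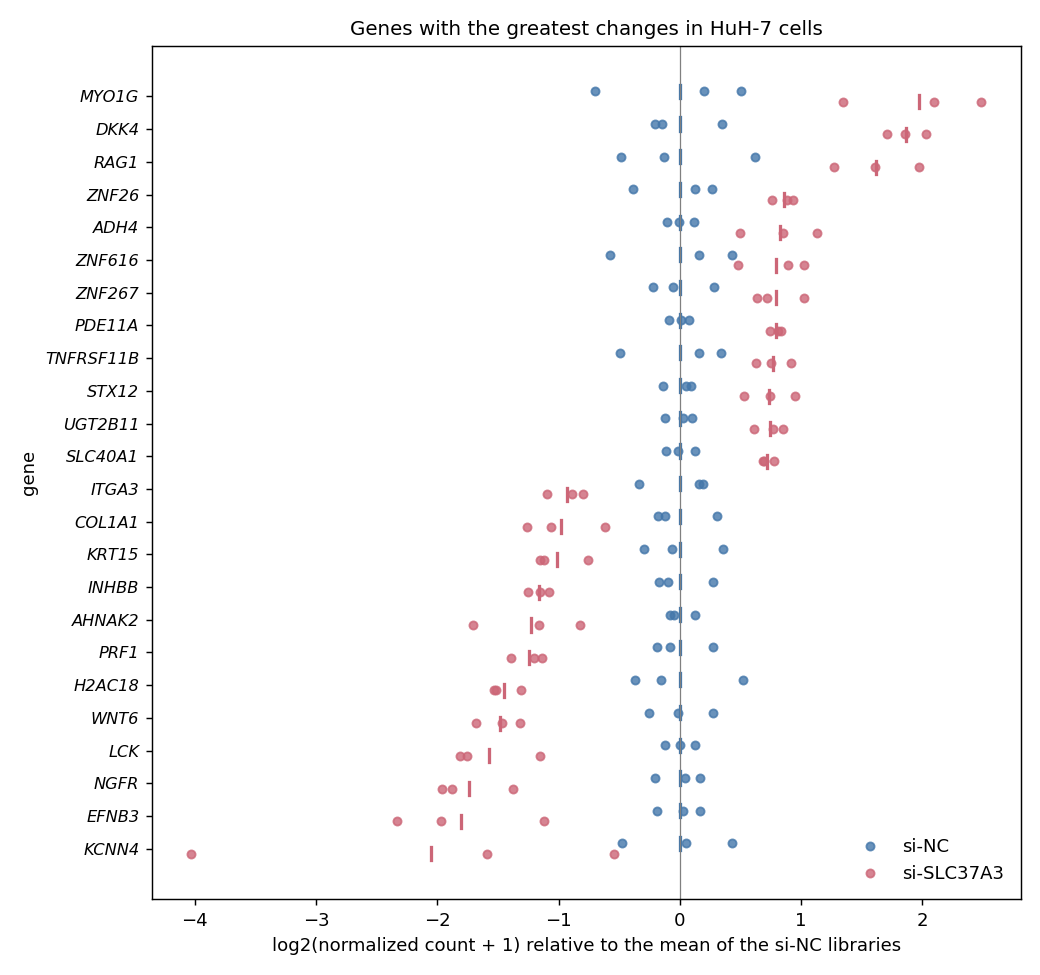
Each row is 1 of the 12 genes with the greatest increase or the 12 with the greatest decrease, each point is 1 library, and the vertical strokes are group means of 3 libraries. The x axis is log2(normalized count + 1) relative to the si-NC mean; DKK4 lies 1.86 higher and NGFR 1.74 lower (-1.74) in si-SLC37A3, with no overlap between the groups.

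Of the 42 gene lists fixed beforehand, 39 had at least 5 members tested, and 7 differed from the rest of the genes with a preset correlation between genes (camera, adjusted p under 0.05). None of the 39 passed with an estimated correlation, where 1 adjusted p was 0.745 and the other 6 of the called lists stood at 0.552. The estimates in called lists ran from -0.028 (Wnt targets) to 0.594 (mitochondrially encoded transcripts), against the preset 0.01. The Wnt call was lost although its estimate lay below the preset. A call lost under this setting therefore does not by itself show that the genes of a list were correlated. At an unadjusted p under 0.05, 14 lists passed camera, and 3 passed fry after adjustment, 1 of them among the 7. The median, the mean and the test differed in sign for mitosis, gluconeogenesis, acute phase, apoptosis, ATF4, ERK, NRF2 and immune markers, none of which camera called, and the median and mean for the untested endothelial markers. The first of the called groups belongs to RNA quality: all 13 mitochondrially encoded transcripts tested lay below 0, with a median log2 fold change of -0.25 (camera, adjusted p = 1.85e-05; adjusted p = 0.552 with an estimated correlation). MT-ND4L passed among all genes and 5 passed when adjusted over the list alone. MT-ND4L was 10111 ± 2380 normalized counts in si-SLC37A3 and 13088 ± 677 in si-NC, with overlapping groups (SD, n = 3 each; limma, adjusted p = 0.00161). Its call was lost under 8 of 22 alternatives, and its adjusted p in the authors' deposited table was 0.836. In that table MT-ND5 alone of the 15 members passed, with a log2 fold change of -0.30 and an adjusted p of 0.0493. MT-CO1, the most abundant member, averaged 269810 ± 28700 against 330330 ± 41100 (SD, n = 3 each; limma, adjusted p = 0.391).

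Genes of the glycolysis list were lower as a group. The median log2 fold change of the 21 glycolysis genes tested was -0.11 (camera, adjusted p = 0.0165; adjusted p = 0.745 with an estimated correlation), and 5 of the 21 lay above 0. In this list 2 genes fell, 1 rose and 18 did not pass, and 7 passed when adjusted over the list alone. SLC2A1, which encodes the glucose transporter GLUT1, fell from 13994 ± 1380 to 7920 ± 872 normalized counts (SD, n = 3 each; limma, log2 fold change -0.82 ± 0.09 SE, adjusted p = 3.9e-16). PGK1, a phosphoglycerate kinase gene, fell by 0.40 on the log2 scale (limma, adjusted p = 0.00104), and the hexokinase gene HK2 rose by 0.36 (limma, adjusted p = 0.00429). The list's call was lost when the values were corrected for GC content (adjusted p = 0.186; range over all alternatives 0.00348 to 0.745). It was also lost without si-NC replicate 1, si-NC replicate 2 or si-SLC37A3 replicate 3, with adjusted p of 0.058, 0.141 and 0.146. In the authors' deposited table SLC2A3, the gene of the glucose transporter GLUT3, also had lower counts, with a log2 fold change of -0.75 and an adjusted p of 6.69e-17. Of 21 genes of gluconeogenesis and glycogen metabolism, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase gene, rose by 0.38 (limma, adjusted p = 0.00137) and 20 did not pass; 1 passed when adjusted over the list alone. None of 10 pentose phosphate genes passed, over all genes or over the list alone; TKT and PGD had log2 fold changes of -0.09 and -0.20.

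Lipid synthesis genes were lower as groups. The 23 cholesterol biosynthesis and SREBP2 genes had a median log2 fold change of -0.14 (camera, adjusted p = 0.0089; adjusted p = 0.552 with an estimated correlation; range over all alternatives 0.000743 to 0.552). DHCR7, the gene of the last enzyme of cholesterol synthesis, fell by 0.28 (limma, adjusted p = 0.0408), a call lost under 10 of 22 alternatives. In this list 2 genes fell, 21 did not pass, and 4 passed when adjusted over the list alone. SREBF2, the gene of the transcription factor SREBP2, had in the authors' deposited table a log2 fold change of -0.33 and an adjusted p of 0.00566. The 19 genes of fatty acid synthesis and lipid storage had a median of -0.10 (camera, adjusted p = 0.0165; adjusted p = 0.552 with an estimated correlation), a call that was lost without si-NC replicate 1 (adjusted p = 0.058; range over all alternatives 0.00451 to 0.552). Here ACSS2, an acetyl-CoA synthetase gene, fell by 0.38 and DGAT1, a triglyceride synthesis gene, fell by 0.34 (limma, adjusted p = 0.004 and 0.00849), 17 genes did not pass, and 3 passed when adjusted over the list alone. Of 19 fatty acid oxidation and PPARA target genes, ACADM, the medium-chain acyl-CoA dehydrogenase gene, rose by 0.49 (limma, adjusted p = 0.00391) and 18 did not pass (camera, adjusted p = 0.218); 1 passed when adjusted over the list alone. The 29 nuclear-encoded genes of oxidative phosphorylation had a median of -0.059 (camera, adjusted p = 0.0625, and 0.0163 with GC correction; range over all alternatives 0.00905 to 0.745) and none passed, over all genes or over the list alone; ATP5F1B and ATP5F1A, the members with the highest levels, had log2 fold changes of -0.14 and -0.05.

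None of the lists of hepatocyte functions passed camera in the main fit, although the amino acid list did under some alternatives. ALB and AFP, the albumin and alpha-fetoprotein genes, had log2 fold changes of 0.10 ± 0.15 and 0.10 ± 0.13 (SE; limma, adjusted p = 0.813 and 0.796), and none of the 15 secreted-protein genes passed over all genes, against 1 adjusted over the list alone. Of 23 bile acid and xenobiotic genes, the export pump genes ABCC2 and ABCB1 rose by 0.45 and 0.39 (limma, adjusted p = 9.09e-05 and 0.0158) and 21 did not pass; the list's median was 0.13 (camera, adjusted p = 0.0675), and 3 passed when adjusted over the list alone. The groups overlapped for ABCB1, and its call was lost under 10 of 22 alternatives, DESeq2 on recovered reads among them (adjusted p = 0.0542). HAMP, which encodes the iron hormone hepcidin, fell by 0.56 (limma, adjusted p = 9.28e-06), while the other 9 acute phase genes tested did not pass; over all 10, 2 passed when adjusted over the list alone. Lower values for other acute phase genes stood in the authors' deposited table, with log2 fold changes of -0.44 for HP, -0.40 for ORM1 and -0.49 for ORM2, the last pair being close paralogs; the median over the 20 acute phase genes of that table was -0.006. The deposited table also gave higher values for the secreted-protein gene APOH and the coagulation gene SERPIND1 (log2 fold changes 0.29 and 0.28), neither of which passed the limma fit (adjusted p = 0.05003 and 0.05185). FTCD, an enzyme gene of histidine breakdown, rose by 0.37 (limma, adjusted p = 0.00659) in a list of 22 amino acid and urea cycle genes with a median of 0.11, of which 1 passed when adjusted over the list alone. That list stood just over the threshold (camera, adjusted p = 0.0509) and passed on ranks, with no filter and with GC correction (adjusted p = 0.0446, 0.0377 and 0.0109; range over all alternatives 0.00826 to 0.552). Of 27 coagulation and complement genes, C4A had a log2 fold change of -0.32 with overlapping groups (limma, adjusted p = 0.0494); it is nearly identical to C4B, and its call was lost in edgeR (adjusted p = 0.0931) and under 18 of 22 alternatives in all. In that list 2 passed when adjusted over the list alone. None of 13 hepatocyte transcription factor genes passed, over all genes or over the list alone; HNF4A and CEBPA both had a log2 fold change of -0.06.

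Wnt target genes were lower as a group. The 19 Wnt and beta-catenin targets tested had a median log2 fold change of -0.19 (camera, adjusted p = 0.0089; adjusted p = 0.552 with an estimated correlation; fry, adjusted p = 0.0314; range over all alternatives 0.00117 to 0.552). In this list 4 genes fell, none rose and 15 did not pass, and 6 passed when adjusted over the list alone. TNFRSF19 fell by 0.49 and CCND1, the cyclin D1 gene, fell by 0.31 (limma, adjusted p = 0.000108 and 0.0194). Among 17 ERK pathway and immediate-early genes, EGR1 rose by 0.49 (limma, adjusted p = 0.00197) and CCND1 fell, with 4 passing when adjusted over the list alone. CCN2, an extracellular signalling protein gene that stands in both the TGF-beta and the YAP lists, rose by 0.44 (limma, adjusted p = 0.0002). In the TGF-beta list ID2 fell by 0.29 (limma, adjusted p = 0.0311), a call lost under 14 of 22 alternatives, and 17 of 19 genes did not pass. In the YAP and TEAD list the receptor gene AXL had a log2 fold change of -0.57 with overlapping groups (limma, adjusted p = 0.0194; edgeR on recovered reads, 0.0527; lost under 13 of 22 alternatives), and 13 of 15 genes did not pass. Adjusted over the list alone, 2 TGF-beta and 4 YAP genes passed. None of 25 PI3K, AKT, mTOR and FOXO genes passed over all genes or over the list alone; AKT1 and AKT2 had log2 fold changes of 0.04 and -0.14.

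Extracellular matrix and integrin genes were also lower as a group, with 4 of 31 lower, 1 higher and 26 not passing, and 5 passing when adjusted over the list alone. The median log2 fold change was -0.13 (camera, adjusted p = 0.0323; adjusted p = 0.552 with an estimated correlation; range over all alternatives 0.00874 to 0.552). The call was lost without si-NC replicate 1, si-SLC37A3 replicate 2 or si-SLC37A3 replicate 3 (adjusted p = 0.103, 0.0633 and 0.114). The laminin gene LAMB3 fell by 0.81 and ITGA3 fell by 0.93, while the integrin gene ITGAV rose by 0.45 (limma, adjusted p = 0.0311, 9.28e-06 and 0.000162). LAMB3 lost its call under 13 of 22 alternatives, and ITGA3 and ITGAV under 1 each. None of 18 genes of the epithelial-mesenchymal transition passed over all genes or over the list alone; FN1, the fibronectin gene, had a log2 fold change of -0.31 ± 0.13 SE (limma, adjusted p = 0.197), and KRT18 of -0.14. FN1 passed in the authors' deposited table, with an adjusted p of 0.0199.

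In the DNA replication list 3 of 27 genes fell and 24 did not pass, among them the helicase gene MCM5, which fell by 0.34 (limma, adjusted p = 0.00817), and CCND1; the median was -0.072, and 3 passed when adjusted over the list alone. That list stood just over the threshold (camera, adjusted p = 0.0501) and passed on ranks, with no filter and with GC correction (adjusted p = 0.0485, 0.0377 and 0.0109; range over all alternatives 0.00866 to 0.552). None of 19 mitosis genes passed over all genes or over the list alone, and PLK1 and CDC20 had log2 fold changes of -0.22 and -0.12. The mitosis list was not called in the main fit but was called, as lower, with GC correction (camera, adjusted p = 0.474 and 0.0163). Of 20 p53 target genes, DDB2, a DNA damage recognition gene, fell by 0.40 (limma, adjusted p = 0.0078) and the rest did not pass; 1 passed when adjusted over the list alone. As a list they passed fry, as lower, and not camera (fry, adjusted p = 0.0314; camera, adjusted p = 0.474). Among 27 apoptosis regulators 2 rose and 25 did not pass; CYCS, the cytochrome c gene, rose by 0.33 (limma, adjusted p = 0.0129), and 7 passed when adjusted over the list alone. None of 15 MYC and ribosome biogenesis genes passed over all genes or over the list alone; NCL and ODC1 had log2 fold changes of 0.17 and -0.13. NOLC1, a member of that list without values per library, passed in the authors' deposited table, with a log2 fold change of 0.56 and an adjusted p of 2.49e-10. Of 32 cytosolic ribosomal protein genes with a median of -0.089 (camera, adjusted p = 0.0509, and 0.0134 with GC correction; range over all alternatives 0.00284 to 0.745), RPS23 and RPS15A passed in opposite directions, 0.34 and -0.31, with overlapping groups, and 2 passed when adjusted over the list alone. The 2 genes have processed pseudogenes that can take reads, and RPS23 did not pass edgeR on recovered reads (adjusted p = 0.0827) and lost its call under 17 of 22 alternatives.

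In the stress and organelle lists, the unfolded protein response genes were slightly higher as a group. Of the 18 genes, 16 lay above 0 and the median log2 fold change was 0.085 (camera, adjusted p = 0.0165; adjusted p = 0.552 with an estimated correlation; range over all alternatives 0.000773 to 0.552). None passed singly, over all genes or over the list alone: HSPA5 and CALR, both endoplasmic reticulum chaperone genes, had log2 fold changes of 0.21 and 0.10. The call was lost without si-NC replicate 3, si-SLC37A3 replicate 2 or si-SLC37A3 replicate 3 (adjusted p = 0.0564, 0.0621 and 0.0885). Both chains of the amino acid transporter LAT1 were lower: SLC7A5 fell by 0.71 and SLC3A2 fell by 0.34 (limma, adjusted p = 5.09e-11 and 0.00695). They belong to the 22 ATF4 targets, of which the other 20 did not pass; over all 22, 2 passed when adjusted over the list alone. In the NRF2 list, the glutathione peroxidase gene GPX2 fell by 0.40 and AKR1C2 fell by 0.37 (limma, adjusted p = 0.000826 and 0.00391), with 19 of 21 not passing and 3 passing when adjusted over the list alone; AKR1C2 has a close paralog in AKR1C1. Of 19 HIF targets, ERO1A rose by 0.36 (limma, adjusted p = 0.0119), SLC2A1 fell and 17 did not pass; 2 passed when adjusted over the list alone. Of 32 lysosome and TFEB target genes, the lysosomal lipase gene LIPA rose by 0.35 and the neuraminidase gene NEU1 fell by 0.32 (limma, adjusted p = 0.00947 and 0.0148), and 30 did not pass; 2 passed when adjusted over the list alone. Among 20 autophagy genes ATG9A fell by 0.31 (limma, adjusted p = 0.0367), with 38.8% of its exonic bases shared with another gene, and 3 passed when adjusted over the list alone. None of 19 interferon response genes passed over all genes or over the list alone (BST2 had a log2 fold change of 0.19). None of 21 NF-kB and cytokine genes passed over all genes, against 1 adjusted over the list alone (SOD2 0.09, ICAM1 -0.08). In the 3 tested genes of the RNA interference machinery none passed over all genes or over the list alone, and XPO5 and DICER1 had log2 fold changes of -0.10 and -0.01.

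**Figure D2:**
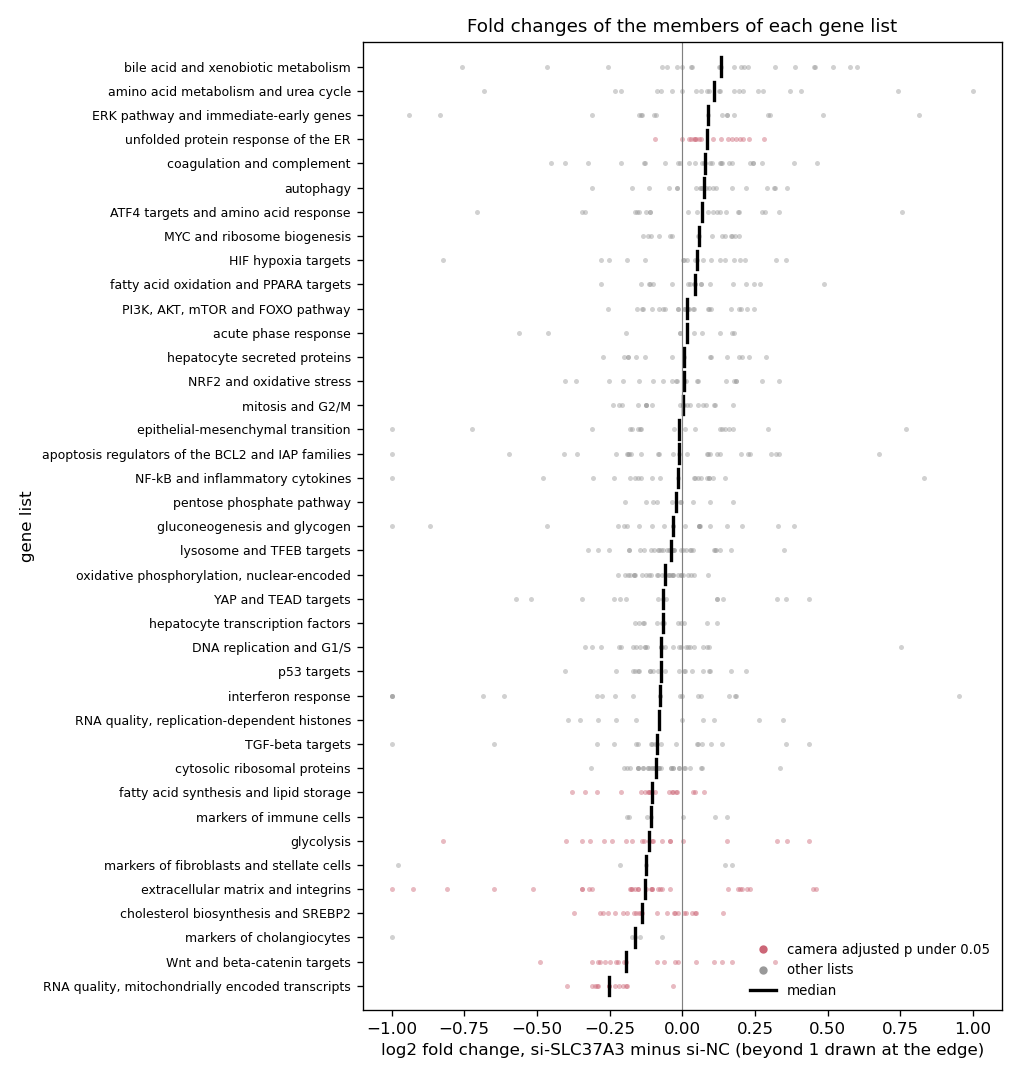
Each row is 1 of the 39 gene lists tested, each point is the log2 fold change of 1 member (si-SLC37A3 minus si-NC, drawn at the edge beyond 1), and black strokes are list medians. The 7 lists with a camera adjusted p under 0.05 are in red, from mitochondrially encoded transcripts (median -0.25) to the unfolded protein response (0.085); none passed with an estimated correlation.

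Markers of other cell types were read as levels, since HuH-7 is a single line. Among 5 fibroblast and stellate cell markers COL1A1 was lower and the rest did not pass, and over all 5 members 1 passed when adjusted over the list alone. PDGFRB, the most abundant, averaged 214 ± 16.3 normalized counts in si-SLC37A3 and 233 ± 21.8 in si-NC (SD, n = 3 each). None of 4 endothelial, 7 immune and 5 cholangiocyte markers passed, over all genes or over the list alone. The endothelial marker TIE1 and the cholangiocyte marker KRT7 had no values per library. Both passed as lower in the authors' deposited table, with adjusted p of 0.00583 and 0.00459. PECAM1 averaged 170 ± 2.92 and 139 ± 10.8, VWF 17.7 ± 2.96 and 27.4 ± 6.68, and CD14 126 ± 2.24 and 127 ± 16.2 normalized counts in si-SLC37A3 and si-NC (SD, n = 3 each). LYZ averaged 9584 ± 527 and 8876 ± 513, KRT19 13528 ± 607 and 14993 ± 1040, and SOX9 4597 ± 250.0 and 4819 ± 182 (SD, n = 3 each). All 5 cholangiocyte markers lay below 0 (fry, adjusted p = 0.0314; camera, adjusted p = 0.113). None of 10 replication-dependent histone genes of the RNA quality list passed, over all genes or over the list alone, with log2 fold changes of -0.16 for H2BC12 and 0.07 for H2AC6.

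Over all 27950 rows of the authors' deposited table, 114 were higher and 144 were lower at an adjusted p under 0.05. Of these 258 rows, 138 were outside the genes with values per library. The genes named next were chosen after their values were seen. In the authors' deposited table IGFBP1, an insulin-like growth factor binding protein gene of the liver, rose from a mean of 1246 to 2638 normalized counts (log2 fold change 1.08, adjusted p = 3.38e-28). DLX1 and the collagen-associated gene CTHRC1 had log2 fold changes of 1.04 and 0.86 in the same deposited table of the authors, and the nucleolar gene NOLC1 one of 0.56. On the lower side, the authors' deposited table gave -1.40 for the keratin gene KRT80, -0.84 for the endothelial receptor gene TIE1 and -0.93 for TTYH1. KRT7, a cholangiocyte marker, was listed there at means of 12.9 and 0 normalized counts. Of the 120 genes the authors' table called among the 6262, 112 were also called in the limma fit, each in the same direction. A further 101 genes were called in the limma fit alone. With the 112 these fall just short of the 214 limma calls, for a reason that was not traced. Among the 101 were KCNN4, EFNB3, RAG1 and ZNF616, with adjusted p of 0.713, 0.435, 0.474 and 0.538 in the authors' deposited table. Their unadjusted p in that table were 0.0385, 0.0133, 0.0161 and 0.0211. The authors' adjustment ran over the genes of the longer table and that of the limma fit over 6051, so the adjusted values are not on one footing.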

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

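The tests with edgeR, DESeq2, GC correction, library-total scaling and the robust prior were chosen after the result was seen. The count of higher genes, 99, lay within 1.5 times of itself under the other filters, scalings and GC corrections, but was 46 at an adjusted p under 0.01 and 2 with glmTreat. The count of lower genes, 115, became 55 and 3 under these, 46 with library-total scaling and 45 in edgeR with library totals. The counts with glmTreat follow from its fold threshold; otherwise the cause was not tested. The 16 genes changed at least 2-fold became 10 with a pseudocount of 0.1, 8 with a filter of 50 reads or with GC correction, 7 with library totals in limma or edgeR, with GC correction and block, or at 0.01, 6 in DESeq2 and 5 with glmTreat. Leaving out 1 library gave 17 to 137 higher genes, 19 to 143 lower genes, and 6 to 23 changed 2-fold. The lowest of each came without si-NC replicate 1, and the highest number of calls without si-SLC37A3 replicate 2. Whether a shared replicate number pairs the samples could not be settled. Deviations of same-numbered libraries correlated at only 0.005, 0.086 and 0.049. Yet 4 of 6 libraries correlated best with their own number, and the slopes on GC content given below had the same order by number in both groups. With the number as a block, 181 genes were higher and 223 lower in limma, 239 and 218 in edgeR, and 12 lists passed. SLC37A3 (-0.48) has values in the authors' table alone: it did not pass at 0.01, and no paired, pseudocount or leave-one-out alternative could be run for it. The deposited unit is the one tested, so the alternative of another unit gave nothing to compare. The count of 7 called lists became 0 with an estimated correlation, with or without GC correction, 3 with fry (1 of the 7, the Wnt targets, with p53 targets and cholangiocyte markers), 12 on ranks and 11 with GC correction, with or without the block; leaving out 1 library gave 5 to 8.

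Lists that passed under no setting tried changed direction in places. Gluconeogenesis did so with fry (adjusted p = 0.778), ranks (0.824), no filter (0.967) and library totals (0.999), acute phase on ranks (0.855), with the block (0.931) and library totals (0.999), lysosome with GC correction (0.847), also with the block (0.843) or an estimated correlation (0.948), ATF4 on ranks (0.855) and NRF2 on ranks (0.958). With 1 library left out, some of these adjusted p-values belong to the other direction: gluconeogenesis 0.687 to 0.981, pentose phosphate 0.384 to 0.981, secreted proteins 0.406 to 0.959, ATF4 0.334 to 0.981, HIF 0.31 to 0.981, NRF2 0.513 to 0.885, PI3K 0.553 to 0.885, immune markers 0.622 to 0.987 and histones 0.606 to 0.885. No called gene that the naming rule took changed sign; over all alternatives, 985 of their calls held and 344 were lost. Depth limits the genes of low count: KCNN4, EFNB3, RAG1, MYO1G, WNT6 and H2AC18 had no adjusted p in DESeq2 and, with KRT15, none under the filter of 50 reads.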

Other observations

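The pathway test, the scan of 7-mers, its letter-order test, the shuffle test of the higher 7-mer, the GC correction and the choice of pathways in this paragraph and of genes in the next came only after results were seen. Among 324 KEGG pathways of 10 to 300 genes, none passed for an excess of called genes (Fisher's exact test, one-sided, Benjamini-Hochberg) and 20 had an unadjusted p under 0.05. The pathway with the lowest unadjusted p, ECM-receptor interaction, had 8 called genes, 2 of them higher (adjusted p = 0.592). All 6 called PPAR signaling genes, all 5 of fatty acid degradation and all 5 of cytochrome P450 drug metabolism were higher, with an adjusted p of 0.592 for each pathway. The direction of calls within a pathway was not tested, and of all 214 calls 46.3% were higher. In the pathway Proteoglycans in cancer 11 of 168 genes were called, 1 of them higher (adjusted p = 0.648).

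Some near-identical copies had unlike fold changes, and the difference between copies was not tested. In the authors' deposited table EIF3CL had a log2 fold change of -1.07 and EIF3C one of -0.63, and NOMO3 had -0.73 where NOMO2 had -0.23 and NOMO1 -0.063. EIF3CL and NOMO3 passed there, and EIF3C, NOMO2 and NOMO1 did not (adjusted p of 0.586, 0.422 and 0.993 in that table). No copy was compared for U2AF1, which had 856 normalized counts in si-SLC37A3 replicate 2 against 39.8 and 32.0 in the other si-SLC37A3 libraries.

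With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 99 higher and 115 lower genes, and the highest count in either direction in another split was 7; the real one alone (1 split) reached that size in each direction. For genes changed at least 2-fold the real value was 16, also reached by 1 split, and the highest other was 1. For gene lists the real value was 7 and the highest other 10, so that 2 splits gave as many.

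A sequence pattern ran through the fold changes, and a candidate explanation is pairing of siRNA seeds with 3′ UTRs. Over 9300 genes, those with AGCTTCT in the 3′ UTR were lower in si-SLC37A3 by a log2 value of -0.036 (1453 genes, z = -7.13), and those with TCGGAGA were higher by 0.096 (181 genes, z = 7.74), which is lower in si-NC. In the 4061 scanned genes with values per library (624 and 75 with a site), the same 7-mers were chosen from libraries 1 and 2 alone, and in libraries 3 they had z = -4.05 and z = 3.11. The 3 leading 7-mers on the lower side overlap, and they follow one another in the SLC37A3 transcript from base 1047, upstream of its 3′ UTR; 18.0% of scanned 7-mers occur somewhere in that transcript. Base composition and chance are argued against. With each replicate number held out in turn, the remaining libraries chose these 7-mers again. In the libraries held out, AGCTTCT lay at least 4.02 SD below the mean of 297 other orders of its letters, and TCGGAGA at least 2.92 SD above that of 116 orders with as many CG pairs. Of 100 shuffles of the fold changes, 0 gave a 7-mer as low and 0 one as high. It remains open what share of the response comes from such pairing, and the siRNA sequences are not given in the sources used here. AGCTTCT stands in the 3′ UTR of 7 called genes that the naming rule took: LCK, SLC2A1, CCND1, DDB2 and RPS15A, which were lower, and RAG1 and PDE11A, which were higher. Of all calls, 28 of 115 lower and 11 of 99 higher genes carry AGCTTCT, against 781 of 5819 uncalled genes (13.4%). TCGGAGA stands in 8 of 99 higher calls, 1 of 115 lower calls (INHBB) and 94 of 5819 uncalled genes (1.6%). Both 7-mers were chosen in fold changes of these same libraries, so these shares are no separate evidence of pairing. A site alone does not show that pairing changed a gene.

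Fold changes also followed GC content: across 5117 genes, which are not independent replicates, the log2 fold change and transcript GC content correlated at r = -0.32 (Spearman's rho -0.38). GC bias of single libraries is a candidate source: the slopes of the libraries differed within a group by up to 2.44 times the difference between group means. The slopes per 10 points of GC were 0.057, 0.105 and -0.041 in si-NC replicates 1, 2 and 3 and -0.016, 0.046 and -0.150 in si-SLC37A3 replicates 1, 2 and 3. They had the same order by replicate number in both groups, and in each same-numbered pair the si-SLC37A3 slope was the lower. The ratio takes no account of this, so it cannot tell bias of single libraries from a difference between the groups. Seed pairing is argued against as the whole source, since r was -0.299 without the genes that carry a 6-base core of either 7-mer, against -0.322 over all genes with a 3′ UTR. A response of the cells to the siRNA that follows GC content stays open and untested. After GC correction 124 genes were higher and 120 lower, 161 of them among the 214 called before, and the glycolysis list was no longer called (adjusted p = 0.186; range over its alternatives 0.00348 to 0.745), its median moving from -0.113 to -0.040.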
